A study of Rattus norvegicus with 4 samples.

How the data were processed

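The series holds 4 arrays, 2 of junctional epithelium and 2 of peri-implant epithelium, and each array's group and replicate number were taken from its title. Per the labels' protocols, male Sprague-Dawley rats received a titanium alloy implant in place of an upper molar at 4 weeks of age, and 20 rats were killed 4 weeks later. Soft tissue was frozen, sectioned and laser microdissected. RNA was extracted with the RNeasy Micro Kit and DNase I treatment, amplified with the Ovation RNA Amplification System V2, and labelled with the Encore Biotin module. Whether each array holds RNA of 1 animal or a pool, and from which side of the mouth or which animals the junctional samples came, is not given in the sources used here.

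The deposited values are log2 signals for 31099 probe sets. The software and normalization used by the authors are not given in the sources used here. The values themselves show that every array was scaled to a mean linear signal of 500.19 after trimming 2% at each end, and that linear values were floored at 1, so that 378 to 729 probe sets per array stand at log2 0. This pattern is what the Affymetrix statistical algorithm gives, an inference from the values. At such a scale, log2 differences between low signals vary widely. The median SD between replicates was 1.44 for probe sets with a mean up to 3, and 0.078 above 11. No array was normalized again for the results reported, and all 4 value columns were used.

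Control probe sets (57) were left out of the tests, which left 31042. Of the control probe sets, 27 for bacterial genes without a clear spike had a median of 3.43 and a highest value of 6.42 on any array, and the latter was taken as the background level. Where an array of the lower group lay at or below it, signals were raised to it before computing a fold, which is then given as "at least". The 18 hybridization controls had a mean of 14.03 on peri-implant array 1 and 13.7 to 13.76 on the others. Genes were taken from the platform's annotation table, where 20826 probe sets carried 1 symbol, 436 several and 9780 none. Each of the 14217 genes was represented by its probe set with the highest mean over the 4 arrays. Symbols were updated by gene identifier, and positions taken, from a reference gene table of the rat assembly GRCr8.

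Peri-implant epithelium was compared with junctional epithelium in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default settings, two-sided, 2 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05, over probe sets and, for named genes and lists, over genes. Because this fit passed 0 probe sets, an alternative planned before the data were examined, eBayes with an intensity trend and robust prior, was given beside it as a second result. That choice was made after the values were seen. A gene is said to have risen or fallen where its adjusted p over all genes passed with an intensity trend, and a list where it passed the list test. A size rule without a test counted probe sets at least 2-fold apart with no overlap of the arrays.

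Before the data were examined, 33 gene lists were fixed from textbook knowledge of oral epithelium, mucosal defence and neighbouring cell types. Members were matched by symbol, then by older symbol, then by a synonym that was no other gene's current symbol. One proline-rich salivary protein whose synonym pointed to another gene was left out. The 32 lists with at least 3 measured members were tested with limma's camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, which found none of the simulated lists below, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. The list of enamel organ and junctional epithelium proteins had 2 measured members (Ambn and Amelx), both below background, and was not tested. Members were also counted with p adjusted over the list alone.

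Named genes followed a rule fixed before the data were examined. It took the 3 title genes, then the 12 genes with the largest difference in each direction among genes past the test, filled by size among genes without overlap of the arrays and with a group mean above 6.98, the median of all values. Symbols of unnamed loci and olfactory receptors were excluded. It then took up to 4 members per list, first those past the test, then by size. As no gene passed over all genes, past the test was read as past over the list alone, and members below background in both groups are not named. The 10 largest differences in each direction among genes past the test with an intensity trend and above background on every array were added after the values were seen.

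On simulated data, with 250 probe sets changed at each of 4 sizes over 5 runs, the default fit found 0 of them, and the fit with an intensity trend found 4.4%, 17.2%, 30.4% and 32.4% for log2 changes of 1, 2, 3 and 4, with 2 false calls. Of 20 simulated lists raised by 1 on the log2 scale, camera found 20 with the preset and 0 with an estimated correlation. With the preset it called 0 of 380 unchanged lists. These lists held genes of high signal with independent noise, so they do not show how often the preset calls unchanged lists of correlated genes. Each run of the probe set simulation changed 200 of 31042 probe sets, and its noise took each probe set's SD between replicates as the true SD.

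The other settings, fixed before the data were examined, were a block for the replicate number, quantile normalization, median centring, 2 filters on low signal, a minimum fold of 1.2 (treat), array weights, the mean of all probe sets of a gene, and leaving out each array in turn. Added after the values were seen were a floor and a filter at the background level, an intensity trend in camera, the alternatives applied to the fit with an intensity trend, the other lists without the title genes, and the comparison of interferon-stimulated with leukocyte genes without Aif1 and with the mean of all probe sets.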

Results

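Gene expression was measured on Affymetrix rat arrays in 4 samples of epithelium captured by laser microdissection. Of these, 2 samples were junctional epithelium, the epithelial collar that seals the gingiva to the tooth, and 2 were peri-implant epithelium, its counterpart around a titanium alloy implant placed at the site of an extracted upper molar. The animals were male Sprague-Dawley rats, 4 weeks old at surgery, and tissue was taken 4 weeks after implant placement from 20 rats. How many animals contributed to each sample is not given in the sources used here. The comparison asks which genes differ in expression between the 2 epithelia, and the series title names Scgb1a1, Lpo and Gbp2 as characteristic of the peri-implant side.

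Signals were on a log2 scale, and the number of arrays limits the precision of every value. The highest signal of 27 bacterial control probe sets on any array was 6.42, which serves here as the background level. Between 54.6% and 56.8% of the 31042 probe sets tested exceeded it on each array. Across probe sets, which are not independent replicates, Pearson's r was 0.914 between the junctional arrays, 0.911 between the peri-implant arrays, and 0.882 to 0.887 between arrays of different epithelia. The difference between 3' and 5' probe sets of Gapdh, a sign of RNA integrity, was 0.68 and 0.58 in junctional and 0.52 and 0.53 in peri-implant samples. That of actin was larger, 1.30 and 1.47 in junctional and 1.37 and 1.26 in peri-implant samples.

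In peri-implant epithelium the transcripts of mucosal defence proteins, interferon-stimulated genes, complement and acute phase proteins, and markers of neutrophils and of macrophages and dendritic cells were higher than in junctional epithelium. Genes of hemidesmosomes and basement membrane attachment, among them the laminin chains Lama3 and Lamb3, were lower as a list. These are list calls with a preset inter-gene correlation, and 0 lists passed camera with an estimated correlation (smallest adjusted p = 0.308 with an estimated correlation). Camera with an estimated correlation also found 0 of 20 simulated raised lists. Its values, given beside each list below, therefore cannot decide whether correlation between genes accounts for a call. Proteins of the cornified cell layer moved in both directions, with Krt10 and Loricrin lower and Sprr2d higher. Scgb1a1, a secretoglobin best known from airway club cells, was 11.13 ± 0.01 in peri-implant and 7.59 ± 0.20 in junctional epithelium (log2 signal, mean ± SD, n = 2 each, as for all values below), an 11.7-fold difference. Lpo, the lactoperoxidase of saliva, milk and airway fluid, was 11.10 ± 0.01 against 6.39 ± 0.41, at least 23.5-fold higher, because 1 junctional array lay below the background level. Gbp2, an interferon-induced GTPase, was 11.17 ± 0.08 against 7.65 ± 0.20, an 11.5-fold difference.

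With limma's default fit these 3 genes each had an adjusted p = 0.0898 over 14217 genes (Benjamini-Hochberg), and did not pass. Adjusted over the list alone, 3 of 3 passed, against 0 over all genes. With an intensity trend in limma's variance prior, adjusted p over all genes was 4.74e-06 for Scgb1a1, 5.75e-06 for Lpo and 4.75e-06 for Gbp2. The series title names these genes for these samples, so their direction is not independent evidence. In the rat assembly GRCr8, Scgb1a1 lies on chromosome 1 from 215406138 to 215409686, Lpo on chromosome 10 from 73104170 to 73124683, and Gbp2 on chromosome 2 from 234005727 to 234021812, and all are protein-coding.

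**Figure D1:**
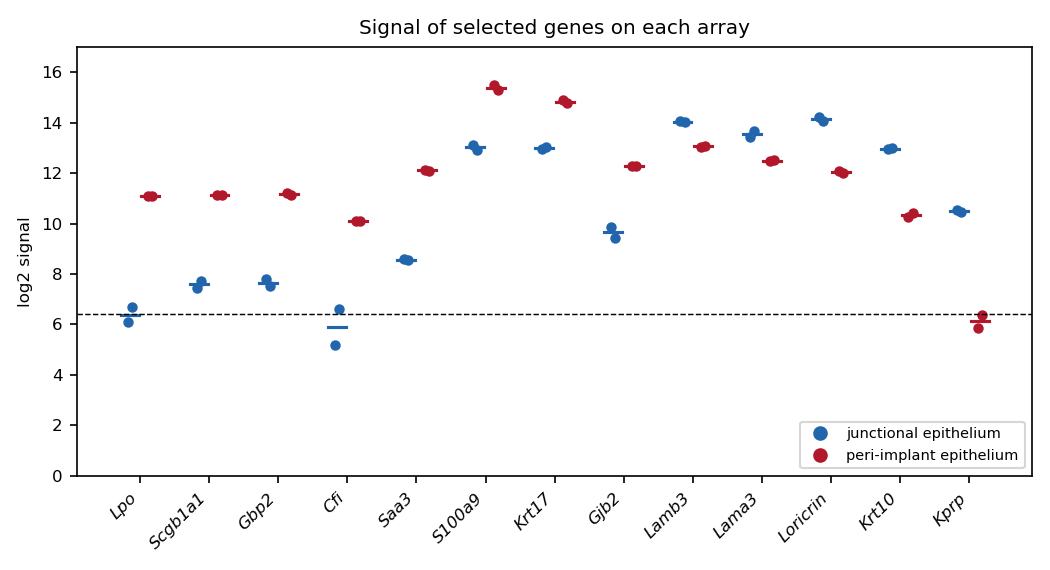
Log2 signal on each array (y axis) of 13 genes (x axis), with junctional epithelium in blue and peri-implant epithelium in red, points for the 2 arrays of each group, bars for group means and a dashed line at the background level of 6.42. Replicates lie close together apart from Cfi in junctional epithelium, with Lpo, Scgb1a1 and Gbp2 near 11.1 in peri-implant epithelium and Krt10 at 12.98 in junctional against 10.35 in peri-implant epithelium.

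Among genes with a signal above background on all 4 arrays, those with the largest increases included an acute phase protein, a secreted phospholipase and a connexin. This set was chosen after its values were seen and holds genes past limma's test with an intensity trend. Above background on all 4 arrays were 8814 genes. Leaving out symbols of unnamed loci and olfactory receptors, which the 8814 include, 850 of them rose and 679 fell. Saa3, an acute phase serum amyloid A, rose from 8.57 ± 0.04 to 12.11 ± 0.02, or 11.6-fold. Sectm1b rose from 7.49 ± 0.37 to 11.19 ± 0.04, and Pla2g2a, a secreted phospholipase that kills bacteria, rose from 9.76 ± 0.35 to 12.50 ± 0.06. Gpr15lg, a chemoattractant for lymphocytes, rose from 9.77 ± 0.12 to 12.66 ± 0.01, and Nppb, which encodes a natriuretic peptide, from 8.13 ± 0.12 to 10.87 ± 0.10. Gjb2, a gap junction connexin, rose from 9.66 ± 0.31 to 12.28 ± 0.01, and Tchh, which encodes trichohyalin, from 9.47 ± 0.01 to 12.00 ± 0.17.

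Krt10, a keratin of suprabasal keratinizing cells, fell from 12.98 ± 0.01 to 10.35 ± 0.12, a 6.18-fold difference. Loricrin, the main protein of the cornified envelope, fell from 14.16 ± 0.12 to 12.04 ± 0.03, and Lce1f, of the late cornified envelope family, fell from 9.32 ± 0.00 to 6.64 ± 0.26. Csn3, which encodes kappa-casein, fell from 12.19 ± 0.02 to 9.54 ± 0.27, and Bglap, which encodes osteocalcin, from 9.55 ± 0.15 to 7.02 ± 0.23. Wif1, a secreted Wnt inhibitor, fell from 9.75 ± 0.00 to 7.35 ± 0.10, Cdkn1c, a cyclin-dependent kinase inhibitor, from 10.05 ± 0.04 to 7.53 ± 0.32, and the protease gene Klk6 from 9.28 ± 0.15 to 7.03 ± 0.35. Col6a5 and Map3k7 also fell, by 2.13 and 2.20 on the log2 scale, with a peri-implant SD of 1.12 for Map3k7. The adjusted p of these genes with an intensity trend ran from 1.67e-06 for Krt10 to 0.0106 for Map3k7, and none passed limma's default fit. How much keratinizing epithelium each sample held was not measured. For Krt10, Loricrin, Lce1f and, below, Kprp, a difference in the tissue captured therefore cannot be told apart from a change in the epithelium. Of 9 listed junctional epithelium and enamel organ proteins, 2 were measured and both lay below background. They therefore cannot show the identity of the junctional samples.

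The genes with the largest differences in each direction were named by a rule fixed before the data were examined. Most had a moderate signal in the epithelium where they were higher and lay at or below background in the other. All 12 that were higher had both junctional arrays at or below background. Ccl3, a chemokine that attracts leukocytes, was 10.39 ± 0.18 in peri-implant epithelium, at least 15.7-fold higher than in junctional epithelium. Prom1 (8.56 ± 0.02), Lcn2, the iron-sequestering protein lipocalin 2 (8.32 ± 0.31), and Tnik (8.07 ± 0.02) were at least 4.42-fold, 3.73-fold and 3.13-fold higher. Meis2, a homeobox transcription factor, Cdkn2a, which restrains the cell cycle, Tnfrsf14, Sim2, Rhoh, Pcp4, Fam13a and Rnase1l2 had peri-implant means from 7.01 to 7.49 and were at least 1.5-fold to 2.1-fold higher.

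In the opposite direction, Kprp, a keratinocyte proline-rich protein of the cornified layer, was 10.49 ± 0.07 in junctional and 6.12 ± 0.38 in peri-implant epithelium, at least 16.8-fold lower. Slc6a15, an amino acid transporter, was at least 4.2-fold lower, and Fam53b, with a peri-implant SD of 2.12, at least 4.22-fold lower. Orc1, a subunit of the origin recognition complex, Lpal2, Ccl21, Ces1d, Ces1e, Xylt1, Trem2, Plcb1 and Sned1 were at least 1.49-fold to 3.02-fold lower. For Fam53b and Trem2, 1 of 2 probe sets had this direction. None of these 24 genes passed limma's default fit over all genes, with adjusted p from 0.0898 to 0.298, and all 24 passed with an intensity trend, where the largest adjusted p was 0.0486, for Ces1e.

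**Figure D2:**
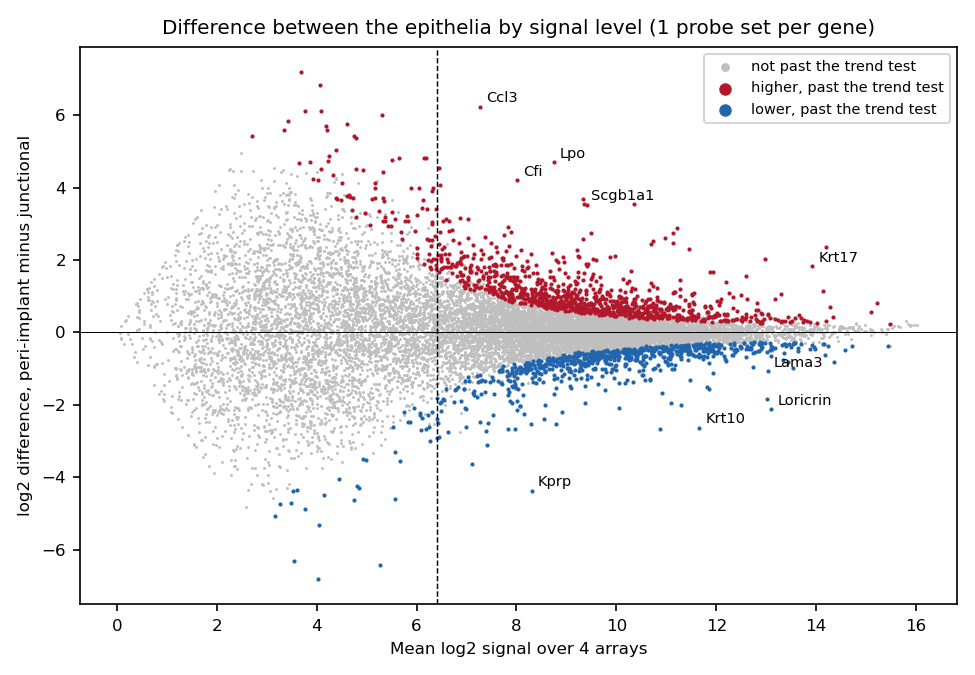
Difference between peri-implant and junctional epithelium (log2, y axis) against mean log2 signal over the 4 arrays (x axis), 1 point per gene, with genes past limma's test with an intensity trend in red (1051 higher) and blue (759 lower) and the rest in grey. The cloud is wide to the left of the dashed background line at 6.42 and narrow at high signal.

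Interferon-stimulated genes rose as a group, with a median log2 difference of 1.07 over 29 measured members, or 0.28 with signals below background raised to it. The list test was limma's camera with a preset inter-gene correlation of 0.01 (adjusted p = 0.000143, but adjusted p = 0.308 with an estimated correlation). In all, 10 members rose, 0 fell and 19 did not pass with an intensity trend, and with the default fit 8 rose when adjusted over the list alone and 0 over all genes. The ubiquitin-like modifier Isg15 rose from 8.04 ± 0.42 to 10.63 ± 0.13, Ifit2 from 7.32 ± 0.05 to 9.13 ± 0.06 and Gbp7 from 6.75 ± 0.18 to 8.43 ± 0.33. Without Gbp2, which the series title names, the median of the list was 1.05 (adjusted p = 0.000246). The lists of macrophage and neutrophil markers also passed as higher in the same samples, but not with an estimated correlation (adjusted p = 0.33 and adjusted p = 0.308 with an estimated correlation).

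Genes of antigen presentation rose as well, in samples where the macrophage and dendritic cell list had a median difference of 0.93. In the MHC class II list, the median difference was 0.86 over 9 members (0.74 with background raised), with 5 rising with an intensity trend, 5 when adjusted over the list alone and 0 with the default fit over all genes (camera, adjusted p = 0.000246, and adjusted p = 0.308 with an estimated correlation). Ctss, a protease that trims the invariant chain, rose from 9.03 ± 0.14 to 10.35 ± 0.04, and Cd74, the invariant chain itself, from 11.97 ± 0.11 to 13.02 ± 0.04. The class II beta chain gene RT1-Db1 rose from 10.22 ± 0.21 to 11.14 ± 0.07. In the MHC class I and antigen processing list the median was 0.58 over 15 members (0.23 with background raised), with 6 rising with an intensity trend, 3 when adjusted over the list alone and 0 over all genes (adjusted p = 0.00882, and adjusted p = 0.308 with an estimated correlation). The immunoproteasome subunits Psmb8 and Psmb9 rose by 1.44 and 1.01 on the log2 scale, and Tapbp, which loads peptides, by 1.15.

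Markers of neutrophils and of macrophages and dendritic cells were higher in peri-implant epithelium. The lists for Langerhans, T and NK, B and plasma, and mast cells did not pass camera (adjusted p from 0.108 to 0.55). The B and plasma cell list passed fry (adjusted p = 0.0183). Their medians were 1.22, 1.02, 0.71 and 0.35, in that order, and 0.52, 0, 0 and 0 with background raised. Only 5 of 19 T and NK, 3 of 9 B and plasma and 1 of 10 mast cell markers exceeded background in either group. Not passing therefore does not show that these cells were unchanged. The neutrophil list had a median difference of 1.42 over 7 measured members (0.80 with background raised), of which 5 exceeded background in either group. Its other members, Mpo, Elane, Prtn3, Ngp, Retnlg and Cd177, were not matched to a gene on the array. In all, 5 rose with an intensity trend, 6 when adjusted over the list alone and 0 over all genes. The list passed camera (adjusted p = 0.000226, and adjusted p = 0.308 with an estimated correlation). S100a9, a calprotectin subunit abundant in neutrophils and in stressed keratinocytes, rose from 13.02 ± 0.15 to 15.39 ± 0.15, the chemokine receptor Cxcr2 from 9.54 ± 0.10 to 10.96 ± 0.01 and the Fc receptor Fcgr3a from 6.57 ± 0.07 to 8.07 ± 0.07. The macrophage and dendritic cell list had a median of 0.93 over 19 members (0.73 with background raised), with 8 rising and 1 falling with an intensity trend, 7 and 1 when adjusted over the list alone and 0 over all genes (adjusted p = 0.000246, and adjusted p = 0.33 with an estimated correlation). Estimated correlations were 0.17 for this list and 0.07 for the neutrophil list. Both exceed the preset 0.01, so the preset may make their p too small. Laptm5 rose from 7.59 ± 0.55 to 9.24 ± 0.06 and Csf1r, the receptor for macrophage colony-stimulating factor, from 7.23 ± 0.34 to 8.65 ± 0.19. Mrc1, the mannose receptor of resident macrophages, fell from 7.57 ± 0.16 to below background, at least 2.22-fold. Aif1 rose by 1.26, from the brighter of its 2 probe sets, while the mean of both gave -0.29.

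Antimicrobial and mucosal defence proteins had a median difference of 0.88 over 14 members (0.56 with background raised), with 8 rising and 1 falling with an intensity trend, 7 and 1 when adjusted over the list alone and 0 over all genes. The list passed camera (adjusted p = 0.00786, and adjusted p = 0.308 with an estimated correlation), also without Lpo (adjusted p = 0.0213). Besides Lpo and S100a9, Duox2, an oxidase that supplies peroxide to lactoperoxidase, rose from background to 7.86 ± 0.26, at least 2.71-fold. Outside the naming rule, the member that fell was the beta-defensin Defb4, by 1.83 on the log2 scale (chosen after its value was seen). The neutrophil list shares 3 of its 7 members with other lists and this list 5 of its 14.

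Complement and acute phase genes had a median difference of 0.91 over 14 members (0.81 with background raised). Of these, 3 (C1qa, C1qb and C1qc) also stand in the macrophage and dendritic cell list. In all, 6 rose with an intensity trend, 7 when adjusted over the list alone and 0 over all genes. The list passed camera (adjusted p = 0.00367, and adjusted p = 0.308 with an estimated correlation). Besides Saa3, the complement regulator Cfi was 10.11 ± 0.02 in peri-implant epithelium, at least 12-fold higher than in junctional epithelium, and C3, the central complement component, rose from 9.46 ± 0.23 to 11.14 ± 0.24. Cytokines and chemokines had a median of 0.34 over 28 members (0.11 with background raised), with 10 rising and 2 falling with an intensity trend, 10 and 2 when adjusted over the list alone and 0 over all genes (adjusted p = 0.0203, and adjusted p = 0.308 with an estimated correlation). The neutrophil attractant Cxcl2 rose from 8.90 ± 0.17 to 11.02 ± 0.04 and the monocyte attractant Ccl2 to 8.76 ± 0.36, at least 4.8-fold. Cxcl14, a chemokine made by resting epithelium, fell from 7.44 ± 0.42 to below background, with 1 of 2 probe sets in this direction. The complement list did not pass without peri-implant replicate 2 (adjusted p = 0.0519), nor the cytokine list without peri-implant replicate 2 (adjusted p = 0.0513) or junctional replicate 2 (adjusted p = 0.0693). The cytokine median was 0.77 without junctional replicate 1, and 0.52 and 0.74 without peri-implant replicate 1 and 2.

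Airway and glandular secretory proteins had a median difference of 1.23 over 21 members, but only 8 exceeded background in either group and the median was 0 with signals below background raised to it. A total of 5 rose with an intensity trend, and 4 rose and 1 fell when adjusted over the list alone, against 0 over all genes. The list passed camera (adjusted p = 0.0274, and adjusted p = 0.614 with an estimated correlation), but not without the title genes Scgb1a1 and Lpo (median 0.77, adjusted p = 0.175), without junctional replicate 1 (median 0.03, adjusted p = 0.446), without peri-implant replicate 2 (adjusted p = 0.134) or with background raised (adjusted p = 0.0701). The estimated correlation of this list was 0.41, above the preset 0.01, so the preset may make its p too small. Besides Scgb1a1 and Lpo, the membrane mucin Muc4 rose from 7.20 ± 0.23 to 9.02 ± 0.02.

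Genes of hemidesmosomes and basement membrane attachment were lower, with a median difference of -0.31 over 14 members. Of these, 5 fell with an intensity trend, 0 rose and 9 did not pass, and 2 fell when adjusted over the list alone, against 0 over all genes (adjusted p = 0.0141, and adjusted p = 0.308 with an estimated correlation). Lama3 and Lamb3, chains of the laminin of epithelial anchorage, fell from 13.56 ± 0.17 to 12.49 ± 0.04 and from 14.03 ± 0.03 to 13.06 ± 0.04. Itgb4, the beta chain of the hemidesmosomal integrin, fell from 14.11 ± 0.00 to 13.65 ± 0.11. Col4a5, a basement membrane collagen chain, was 8.66 ± 0.19 against 7.66 ± 0.58 and did not pass. The list did not pass without junctional replicate 2 (adjusted p = 0.0639) or peri-implant replicate 1 (adjusted p = 0.0565). In the same samples the median differences of fibroblast (0.33), neutrophil (1.42) and macrophage and dendritic cell markers (0.93) were positive, and so were those of simple and basal keratins (0.19) and cell-cell junction genes (0.18). The keratin list did not pass, and the junction list passed under some settings. The share of epithelial cells in each sample was not measured.

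Genes of squamous differentiation moved in both directions, and the list did not pass camera (adjusted p = 0.334), although it passed fry (adjusted p = 0.0335). Of 17 members 5 rose and 7 fell with an intensity trend, and adjusted over the list alone 3 rose and 4 fell, against 0 over all genes. The median was 0.02 while the mean, -0.35, and the direction of the test were negative. Sprr2d, a small proline-rich envelope protein, rose from 10.29 ± 0.17 to 12.60 ± 0.03, while Cdsn, which encodes corneodesmosin, fell from 10.57 ± 0.23 to 8.99 ± 0.15, beside Krt10 and Loricrin. On chromosome 2, Sprr2d (180565685 to 180566282) lies between Loricrin (180253674 to 180256572) and Kprp (181125530 to 181129828). Among 8 simple and basal keratins 2 rose and 1 fell with an intensity trend, 1 rose when adjusted over the list alone and 0 over all genes, and the list did not pass (adjusted p = 0.334). Krt17, a keratin induced in wounded epithelium, rose from 13.00 ± 0.07 to 14.83 ± 0.09 and Krt15 from 13.23 ± 0.02 to 13.65 ± 0.08, whereas Krt7 fell from 13.64 ± 0.03 to 13.09 ± 0.10. Of 18 cell-cell junction genes 4 rose with an intensity trend, 1 when adjusted over the list alone and 0 over all genes (adjusted p = 0.0598). The junction list passed with an intensity trend in camera (adjusted p = 0.00915), with background raised (adjusted p = 0.00394) and with fry (adjusted p = 0.00666). The 4 genes included Gjb2, Gjb6 (7.88 ± 0.28 to 8.95 ± 0.21) and the tight junction protein F11r (12.52 ± 0.01 to 13.01 ± 0.03).

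Of the lists for neighbouring tissues, 4 passed camera with the preset correlation, fibroblast and connective tissue markers as higher and endothelial, melanocyte and nerve, and blood haemoglobin genes as lower, and 0 passed with an estimated correlation. Among 22 fibroblast markers 8 rose and 2 fell with an intensity trend, 4 and 2 when adjusted over the list alone and 0 over all genes (median 0.33, adjusted p = 0.0274, and adjusted p = 0.308 with an estimated correlation). Ogn, which encodes osteoglycin, rose to 7.83 ± 0.08, at least 2.66-fold, and the collagen cross-linking enzyme Lox rose from 7.39 ± 0.15 to 8.67 ± 0.29, whereas Pdgfra fell from 9.70 ± 0.03 to 8.66 ± 0.17. The fibroblast median was 0.20 with the mean of all probe sets of a gene (adjusted p = 0.0423). Among 14 endothelial markers 2 fell with an intensity trend, 1 when adjusted over the list alone and 0 over all genes (median -0.55, adjusted p = 0.0358, and adjusted p = 0.503 with an estimated correlation). Egfl7, secreted by endothelium, fell from 9.23 ± 0.15 to 7.86 ± 0.09.

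Of 10 melanocyte and nerve markers 0 passed with an intensity trend (limma, default fit 0 adjusted over the list alone and 0 over all genes), and only 3 exceeded background (median -0.72, adjusted p = 0.021, and adjusted p = 0.308 with an estimated correlation). Of 3 haemoglobin and erythroid genes 1 fell with an intensity trend, 2 when adjusted over the list alone and 0 over all genes (median -0.71, adjusted p = 0.021, and adjusted p = 0.308 with an estimated correlation). Hbb was 13.81 ± 0.01 in junctional and 13.57 ± 0.04 in peri-implant epithelium and did not pass. With background raised, the endothelial (median -0.32, adjusted p = 0.0987), melanocyte (median 0, adjusted p = 0.438) and haemoglobin (median -0.24, adjusted p = 0.0717) lists no longer passed. The endothelial median was -0.36 without junctional replicate 2, and the melanocyte median -1.32 without junctional replicate 1. Neither the fibroblast nor the endothelial list passed without junctional replicate 2 (adjusted p = 0.167 and 0.262) or peri-implant replicate 2 (adjusted p = 0.0659 and 0.192), nor the fibroblast list with median centring (adjusted p = 0.0545). Without junctional replicate 2 the melanocyte and haemoglobin lists did not pass either (adjusted p = 0.0709 and 0.0606), nor the haemoglobin list without junctional replicate 1 (adjusted p = 0.0781).

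**Figure D3:**
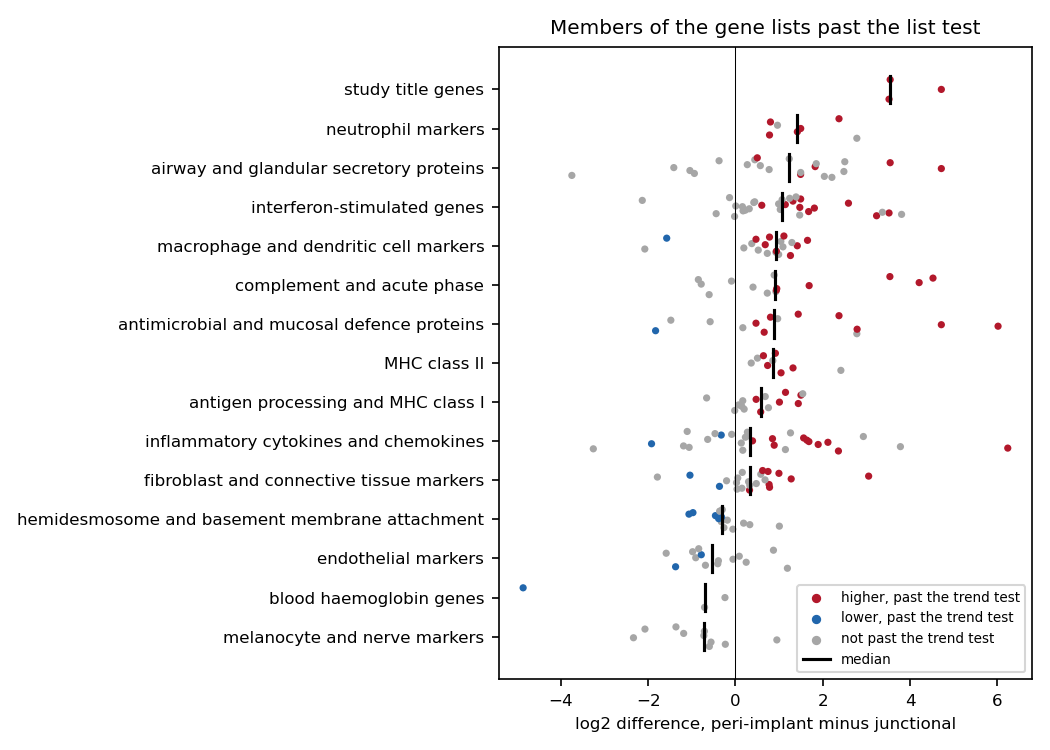
Log2 difference between peri-implant and junctional epithelium (x axis) of each measured member of the 15 gene lists past camera's test (y axis), with members past limma's test with an intensity trend in red (higher) or blue (lower), the rest in grey, and a black bar at each list's median. Medians run from -0.72 for melanocyte and nerve markers to 3.54 for the title genes, which the series title names for these samples.

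Over all probe sets, limma's default fit passed 0 at a Benjamini-Hochberg adjusted p of 0.05, with a smallest adjusted p = 0.125, although 5247 had an unadjusted p under 0.05 where 1552 would be so by chance. With an intensity trend and robust prior, limma passed 2762 probe sets, 1470 higher and 1292 lower in peri-implant epithelium. By size, 3360 probe sets were at least 2-fold higher and 2764 at least 2-fold lower with no overlap of the arrays. In all, 53.3% of probe sets showed no overlap in either direction, against an average of 33.3% by chance. Probe sets on the same arrays are not independent, so neither this share nor the count of unadjusted p tests the grouping. Of 32 lists tested, 15 passed camera, 11 higher and 4 lower, including the title genes (adjusted p = 0.000246, and adjusted p = 0.308 with an estimated correlation). The series title names those genes for these samples, so the pass of their list is not independent evidence. With an estimated correlation 0 lists passed camera, against 16 with fry, and 16 with camera and an intensity trend. Camera with an estimated correlation also found 0 of 20 simulated raised lists, so it cannot decide between these counts.

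Without a filter on low signal, the default fit found 0 of 250 simulated probe sets changed by 4 (log2), and the intensity trend found 32.4%. Each simulated run changed 200 of 31042 probe sets, whereas 5247 in the data had an unadjusted p under 0.05 (limma, default fit). Adjustment is stricter where fewer probe sets change, so the simulation does not by itself account for the 0 calls in the data. With the lower 50% of mean signals left out, the default fit passed 1838 probe sets on the same 4 arrays. The calls with an intensity trend also rest on all 4 arrays, as 76 and 73 probe sets passed without junctional replicate 1 or 2, and 353 and 278 without peri-implant replicate 1 or 2.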

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

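The floor, the filter at the background level, the intensity trend in camera, the lists without the title genes and every alternative to the fit with an intensity trend were chosen after seeing the data. With limma's default fit, 0 probe sets passed in either direction under the block for replicate number, quantile normalization, median centring, the filter on the lowest 25% of mean signals, the minimum fold, array weights and each array left out. Higher and lower calls numbered 1005 and 833 with the lower 50% of mean signals left out, 188 and 162 with the floor, 746 and 519 with the filter at the background level, and 1470 and 1292 with an intensity trend. The filters test fewer probe sets and drop the most variable ones. The floor gives all signals at or below background the same value, which by construction removes the spread between them. Otherwise the cause was not tested.

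Counts of at least 2-fold higher and lower probe sets were 2001 and 1579 with the lowest 25% left out, 753 and 553 with the floor, and 1377 and 1029 with the filter at the background level, which by construction remove low signals. They ranged from 4055 to 5201 and from 3561 to 4474 with 1 array left out, where a lone array overlaps less often. With an intensity trend, counts were 2226 and 1976 with the block and ranged from 59 to 146 and from 14 to 207 with 1 array left out, where 1 residual degree of freedom remained and the lone array was assumed to vary like the other group. The labels tie no arrays into pairs, and the deviations of same-numbered arrays correlated at 0.0394 across probe sets. The share of higher calls was 53.2% as deposited, 50.6% after quantile normalization and 47.9% after median centring.

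The number of lists past camera was 0 with an estimated correlation (which found 0 of 20 simulated lists) and 9 to 14 with 1 array left out, with 9 without junctional replicate 2 and 10 without peri-implant replicate 2. It was 12 to 16 under the others. The cytokine (adjusted p = 0.0687) and fibroblast (0.0527) lists did not pass with the block, the melanocyte list not with the mean of all probe sets (0.0986) or a trend in camera (0.116), nor it (0.175), the airway (0.112) and the endothelial list (0.138) with fry. Of 123 named genes with a group mean above background, 122 kept their direction under every alternative that tested them. Much of this count was fixed in advance, because the intensity trend, the minimum fold, the filters and the block leave a difference unchanged. Genes without overlap of the arrays also cannot reverse when an array is left out or reweighted. Aif1 was -0.29 with the mean of all probe sets of a gene (the cause was not tested). A pseudocount was not tried, as values were on a log2 scale. Signal over background limits the rest: below 6.42 a difference gives only a bound.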

Other observations

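Several gene groups outside the main account had single members with large differences while the list did not pass camera. Among 28 antioxidant and detoxification enzymes 7 rose and 5 fell with an intensity trend (list adjusted p = 0.683). The mitochondrial superoxide dismutase Sod2 rose from 11.04 ± 0.01 to 12.71 ± 0.11, and the metallothioneins Mt1 and Mt2A rose by 1.40 and 1.08 on the log2 scale. Among 25 metalloproteinase and wound migration genes 3 rose and 2 fell (adjusted p = 0.915). Plat, the tissue plasminogen activator, rose from 11.97 ± 0.05 to 13.99 ± 0.02, Tnc, which encodes tenascin-C, from 7.93 ± 0.08 to 9.03 ± 0.28, and Fn1, which encodes fibronectin, from background to 7.70 ± 0.12. Among 19 immediate early and heat shock genes 5 rose and 2 fell (adjusted p = 0.0742, but 0.0328 with an intensity trend in camera and 0.00966 with fry). Fos rose from 9.90 ± 0.02 to 12.37 ± 0.03, with 1 of 2 probe sets in this direction, and Egr1 from 11.01 ± 0.02 to 12.03 ± 0.03. Of 12 bone and cementum markers 3 rose, among them Postn, and 1, Bglap, fell (adjusted p = 0.309).

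Of 28 proliferation genes 2 rose and 1 fell (adjusted p = 0.683), with Mcm5 at 10.65 ± 0.08 in peri-implant against 9.71 ± 0.10 in junctional epithelium. Of 15 circadian clock genes 2 rose and 1 fell (adjusted p = 0.7, with a median of -0.03 and a mean of 0.11): Dbp rose by 1.48 and Per3 by 1.40, and Clock fell by 0.89 on the log2 scale. Of 11 lipid barrier genes 0 rose and 2 fell (adjusted p = 0.309, with a median of -0.08 and a mean of 0.03), and Alox15 fell from 9.10 ± 0.28 to 7.06 ± 0.45. Of 27 Wnt, Notch, TGF-beta and BMP genes 2 rose and 6 fell (adjusted p = 0.411, with a median of -0.01 and a mean of 0.01), and Dkk3 fell from 9.40 ± 0.37 to 8.11 ± 0.15, with 2 of 4 probe sets in this direction. Of 5 Langerhans cell markers 2 rose and 1 fell (adjusted p = 0.31), with Ccr6 rising from 6.63 ± 0.10 to 7.85 ± 0.26. Of 19 T and NK cell markers 1 rose and 1 fell (adjusted p = 0.309), of 9 B and plasma cell markers 1 rose (adjusted p = 0.108, but 0.0183 with fry), and of 10 mast cell (adjusted p = 0.55) and 17 skeletal muscle markers (adjusted p = 0.449) 0 passed limma with an intensity trend. These 4 lists had 5, 3, 1 and 5 members above background. The 15 salivary gland products did not pass as a list (camera, adjusted p = 0.309, and fry, adjusted p = 0.058), and 2 exceeded background. With an intensity trend 2 rose and 0 fell, and 3 rose and 0 fell when adjusted over the list alone.

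The tests in the following paragraphs were all chosen after the values they use were seen. The 4 arrays can be divided 2 and 2 in 3 ways, which is too few for a share under 0.05. The real division gave 2762 probe sets with an intensity trend and the highest of the others 0, and by size and no overlap it gave 6124 against 3366. In each case 1 of the 3 divisions, the real one, gave as many.

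Lpo is a product of glands, so salivary tissue captured with the peri-implant samples is a candidate source of its signal. Scgb1a1 is not among the listed salivary gland products, and the following comparison does not cover it. Of 13 other salivary gland products (leaving out Lpo and the widely expressed Cst3), 0 had a peri-implant mean above the background level of 6.42, and the highest was 5.97. That argues against gland tissue that makes these 13 products as the source of the Lpo signal of 11.10, although no gland sample was there to show that their probe sets detect them. Minor glands that make other products remain open. Muc19, Dcpp1 and Prp2 were not matched to a gene on the array, and some other glandular secretory genes, chosen after their values were seen, were higher. With an intensity trend Bpifb1 rose from 7.08 ± 0.11 to 8.57 ± 0.03 and Wfdc2 from 12.78 ± 0.00 to 13.28 ± 0.03, while Pigr, at 7.07 ± 0.12 against a level below background, did not pass (adjusted p = 0.0563). Expression by the peri-implant epithelium itself, or by other cells within it, also remains open and was not tested.

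The rise of interferon-stimulated genes may reflect a larger share of leukocytes in peri-implant epithelium, with no change per cell. Among interferon-stimulated genes above background on every array, which leaves out those that rose from below it, 17 had a median difference of 0.99. The differences of 5 leukocyte genes (Ptprc, Laptm5, Tyrobp, Fcer1g and Aif1) had a median of 1.11 and ran from 0.68 to 1.65. The difference of the medians was -0.12 (95% bootstrap interval -1.10 to 0.69), too wide to decide. The bootstrap resampled genes, so its intervals here do not cover variation between arrays or animals. Of the 17 genes, 4 exceeded the largest leukocyte difference, Gbp2 at 3.52 among them. The value of Aif1, 1.26, came from the brighter of its 2 probe sets. With the mean of all probe sets of a gene, Aif1 was -0.29, the leukocyte differences ran from -0.29 to 1.45, and the difference of the medians was 0.15 (-0.97 to 1.28). Without Aif1 it was 0.04 (-1.15 to 0.71). A change of cell mixture and a change of expression per cell cannot be told apart here.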
